A study of Mus musculus with 10 samples.

How the data were processed

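H3K4me3, the trimethylated form of lysine 4 on histone H3, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in neuronal nuclei of the mouse hippocampal area CA1. Per the labels' protocols, CA1 was dissected and frozen, nuclei carrying the neuronal protein NeuN were sorted, and 0.2 µg of chromatin was precipitated with an H3K4me3 antibody. Libraries were read as single 50-bp ends. The 8 H3K4me3 libraries come from 4 CaMKIIδC transgenic samples and 4 littermate controls, grouped by their titles, and the labels give an age of 3 months and male sex for all 8. The 2 remaining samples, called input in the title and IgG in the antibody label, number 1 per genotype and were not analysed here. The protocol text also mentions the drug vorinostat, but no sample used here carries a drug label. The letters in the sample descriptions and those in the names of the peak lists do not match, while the group names in both do. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

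Per the submitters' processing notes, the tools were FastQC 0.11.5, Bowtie2 2.0.2, SAMtools 1.3.1, deepTools 3.0.1, MACS2, DiffBind and limma, with the genome build mm10. Their roles and settings are not given in the sources used here, nor is which library served as background for which peak list. The authors deposited 1 peak list per library, in the layout that MACS2 writes, with no header. Each deposited row holds a position, a whole-number score, a fold enrichment at the summit, and the −log10 of a p-value and of a q-value. The score and the fold enrichment are the authors' own values for that peak and were used only to rank peaks within a list. The smallest deposited −log10 q-values lay between 1.31 and 1.42, and between 80 and 93 peak numbers per list were missing from the caller's numbering, removed by a filter of the authors that the sources used here do not describe. The lists hold no read counts, so the depth is unknown. A deeper library or a better precipitation gives more and wider peaks, and each list was called on its own library, so numbers and widths of peaks can differ between libraries for that reason alone.

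Overlapping or touching peaks within a library were merged, which left the number of peaks unchanged. Gene positions came from the RefSeq annotation of GRCm38.p6, whose coordinates are those of mm10. The copy used here gives the start and end of a gene but no strand, start site or exon. The promoter was therefore taken as the gene end, of both ends, whose window of 2 kb to each side had the higher mean coverage over all 8 libraries, where the plan had named annotated start sites. For 12936 genes that end had at least 2 times the coverage of the other end. Positions inside a gene could not be divided into exons, introns or untranslated regions. Of 21887 protein-coding genes, 14753 (67.4%) had a peak in this window in at least 4 of the 8 libraries and were tested. The measure of breadth was the length covered by peaks in the window, as log2(bp + 100 bp), centred on each library's median over promoters with a peak in all 8. Fold changes on this scale understate the change of thinly covered promoters. Covered length could not exceed the window of 4001 bp, so peak length beyond it went unmeasured. Breadth was compared with limma 3.58.1 in R 4.3.3 (moderated test, trended and robust variance) with Benjamini-Hochberg adjustment at 0.05. The same fit was made for regions, formed as the union of the 8 lists and kept where at least 2 libraries had a peak, an overlap of 1 bp being enough. Regions with a peak in all 4 libraries of a group and in none of the other were part of this fit and were also listed by presence alone, without a further test per region, since no assignment of 4 against 4 gives an exact permutation p under 0.0286. Summaries per library were compared with exact two-sided permutation tests over 70 assignments, adjusted over 6 summaries.

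Before the data were examined, 23 gene lists, the rule for named genes and most of the other settings tried were fixed. The lists cover glutamatergic synapse, immediate early genes, voltage-gated ion channels, CaM kinases, H3K4 and acetylation enzymes, the unfolded protein, hypoxia and glucocorticoid responses, oxidative phosphorylation, ribosomal proteins, inflammation, neurodegeneration, developmental transcription factors, and markers of CA1, CA3, dentate gyrus, interneurons, astrocytes, oligodendrocytes, microglia, endothelium and cardiomyocytes. All 392 gene symbols in them were found in the annotation, Ero1l under its newer symbol Ero1a. Lists were tested with camera (preset correlation 0.01, and estimated) and with fry, both in limma. The named promoters were the 5 with the smallest p in each direction, since none passed, the 2 with the smallest p in each list (or members past 0.05 adjusted over the list alone, of which there were none), and Camk2d, Camk2a, Kmt2a, Kmt2b, Kmt2d, Setd1b, Bdnf, Arc and Fos. The named regions were the 3 widest in each direction among those present in 1 group alone. A few items that the rule selects are not reported here, though they stayed in the fits and list tests. Items named outside this rule are marked as chosen after their values were seen.

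The fits were tested on simulated data, with 200 changes planted. Values were drawn independently around the real mean of each promoter or region, with its real spread within groups. The simulation held no absent peaks and, apart from set library shifts, no structure shared between libraries, so recovery in the real data may differ. At promoters, 55 of 100 planted changes of 1.5-fold and 78 of 100 of 2-fold were recovered, with 8 false calls. For regions these numbers were 6 and 9 of 100, with 2 false calls. The other settings fixed in advance for promoters or regions were a replicate block, no centring, quantile normalization, pseudocounts of 10 and 500 bp, equal numbers of top-ranked peaks per library, windows of 1 and 5 kb, other limits on the number of libraries, ordinary variances, merging of peaks within 500 bp, and leaving out each library in turn. For gene lists only the block, no centring, equal numbers of peaks, the estimated correlation and leaving out libraries were fixed in advance. Added after seeing the data were array weights, the whole gene as window, autosomes only, equal numbers of top autosomal peaks, and a covariate for libraries with over 10000 peaks on the X chromosome. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.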

Results

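The comparison addresses whether overexpression of CaMKIIδC, a splice form of the delta subunit of calcium/calmodulin-dependent kinase II used in mice to produce heart failure, goes along with altered H3K4me3 in neurons of hippocampal area CA1. H3K4me3 marks the promoters of active or poised genes. Peak lists of 4 transgenic and 4 littermate control libraries were compared, from NeuN-sorted nuclei of mice aged 3 months. The control lists held 51903, 65600, 66811 and 54597 peaks in replicates 1 to 4, covering 37.5, 42.7, 42.7 and 43.1 Mb. The transgenic lists held 102285, 63921, 60388 and 66560 peaks, covering 57.7, 45.8, 45.2 and 48.8 Mb. The number of reads behind each list is unknown. On average 59.7% ± 1.79 (SD, 6 pairs) of the covered length was shared between control libraries, 56.3% ± 6.26 (6 pairs) between transgenic libraries and 57.3% ± 5.94 (16 pairs) between the groups, and without transgenic replicate 1 62.0% between transgenic libraries and 60.4% between the groups. No lists were identical.

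CA1 neuronal chromatin carried H3K4me3 at the promoters of synaptic, immediate early and ribosomal protein genes in all 8 libraries. This held for 29 of 30 genes of the glutamatergic synapse, all 22 immediate early genes, 18 of 20 voltage-gated ion channels, 11 of 13 CaM kinase and calmodulin genes, 16 of 17 neurodegeneration genes, all 25 ribosomal protein genes, 24 of 26 nuclear genes of oxidative phosphorylation and 19 of 20 genes of the unfolded protein response. It held for 18 of 21 H3K4 methyltransferases and demethylases, 17 of 20 deacetylases and acetyltransferases, 15 of 17 hypoxia genes, 12 of 14 glucocorticoid-responsive genes and 10 of 20 inflammatory genes. Of developmental transcription factors, among them Hox and Pax genes, 4 of 25 had a peak in all 8 libraries. Among neuronal markers the counts were 6 of 9 for CA1 pyramidal cells, 6 of 7 for CA3, 7 of 10 for the dentate gyrus and 12 of 14 for interneurons. Among markers of cells that the NeuN gate should remove, they were 6 of 12 for astrocytes, 4 of 14 for the oligodendrocyte lineage, 3 of 10 for endothelium and 1 of 13 for microglia, and for cardiomyocyte genes 1 of 13.

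Among the widest H3K4me3 regions, picked after their values were seen, were those at Mir9-2, Pou3f3, Myt1l and Grin2b (positions in mm10). The region from 83718528 to 83741223 on chromosome 13, over the microRNA gene Mir9-2 and 51449 bp from Mef2c, a transcription factor gene of neuronal differentiation, was covered over 21114 ± 287 bp in transgenic and 20348 ± 207 bp in control libraries (SD, n = 4 each). The region at Pou3f3, a POU-domain transcription factor gene on chromosome 1 (42683992 to 42702747), was covered over 16700 ± 547 and 15650 ± 977 bp. Myt1l, a neuronal zinc finger gene on chromosome 12 (29525673 to 29539632), had 13365 ± 107 and 13319 ± 165 bp. Grin2b, which encodes an NMDA receptor subunit, on chromosome 6 (136163078 to 136174808), had 10740 ± 248 and 10448 ± 251 bp.

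No promoter differed in H3K4me3 breadth inside its window between transgenic and control libraries at an adjusted p of 0.05 in limma, among 14753 tested. The promoters with the smallest p were wider in the transgenic libraries at secretoglobin, olfactory receptor, oogenesin and cytochrome P450 genes, none of which passed. Scgb2b21 (secretoglobin; promoter at 33520455 on chromosome 7) had 2676 ± 502 bp covered in transgenic and 1318 ± 86.8 bp in control libraries (SD, n = 4 each), a log2 difference of 0.93 ± 0.13 (SE, limma adjusted p = 0.302). Olfr122, an olfactory receptor gene at 37772620 on chromosome 17, had 1552 ± 356 and 498 ± 152 bp, a log2 difference of 1.45 ± 0.21 (limma adjusted p = 0.302). Scgb2b3, at 31359038 on chromosome 7, differed by 0.75 ± 0.11. Oog3, at 144162651 on chromosome 4, differed by 2.07 ± 0.33, and Cyp2b19, at 26757142 on chromosome 7, by 1.06 ± 0.18 (both limma adjusted p = 0.344).

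On the lower side the promoters with the smallest p were those of Hrh3, Igsf8, Jdp2, Mob2 and Rab33b, with log2 differences of -0.19, -0.20, -0.20, -0.21 and -0.22 and adjusted p from 0.662 to 0.838. Hrh3, the histamine H3 receptor gene, at 180104484 on chromosome 2, had 2132 ± 90.6 bp in transgenic and 2414 ± 112 bp in control libraries. Igsf8, an immunoglobulin superfamily gene at 172312367 on chromosome 1, had 2560 ± 126 and 2916 ± 138 bp. Without adjustment, 413 promoters had p under 0.05 on the higher and 195 on the lower side (486 and 53 without centring, 360 and 252 with quantile normalization), and with ordinary instead of trended and robust variances limma called 4 higher and 1 lower. For 12012 of the tested promoters (81.4%) the 95% confidence interval of the difference lay within 1.5-fold in both directions. Promoters that filled the window of 4001 bp in controls, such as Dusp6 in all 4, could not show widening. The 4 transgenic values lay wholly on 1 side of the 4 control values at 2.35% of promoters, where chance gives 2.86%.

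The promoter of Camk2d, the endogenous gene of the overexpressed kinase, at 126595487 on chromosome 3, carried 1459 ± 212 bp of H3K4me3 in transgenic and 1442 ± 83.5 bp in control libraries (SD, n = 4 each). Its log2 difference was -0.01 ± 0.09 after centring and 0.01 without it. The H3K4me3 region there ran from 126595898 to 126599299, past the end of the window at 126597487, so part of its length was not measured. Over the whole region 2455 to 3344 bp were covered in transgenic and 2633 to 3148 bp in control libraries. Camk2a, the main forebrain kinase of this family, differed by -0.03 ± 0.07, and transgenic replicate 1 had the lowest Camk2d value of its group (1142 bp). The gene Myh6, whose promoter is commonly used to drive cardiac transgenes, had no peak in any library. Genes of H3K4 methyltransferases had log2 differences of -0.06 (Kmt2a), 0.04 (Kmt2b), -0.06 (Kmt2d), -0.05 (Setd1b) and 0.07 (Setd1a), and activity-regulated genes of 0.06 (Bdnf), -0.03 (Arc) and -0.06 (Fos). None passed (limma adjusted p of at least 0.99 for each).

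None of the 22 gene lists with at least 2 tested genes differed between the groups by camera, and no member passed 0.05 adjusted over the list alone. The oligodendrocyte lineage list had the smallest p, with 4 of 5 tested members lower in the transgenic libraries (median log2 -0.26, camera adjusted p = 0.191, adjusted p = 0.565 with an estimated correlation). By fry, which asks whether a list's genes move 1 way without comparing them with other genes, its adjusted p was 0.00487. Without centring its fry adjusted p was 0.106 and its camera adjusted p was 0.0352 (0.399 with an estimated correlation). Its member Cnp, a myelin enzyme gene, had 867 ± 13.7 bp in transgenic and 1039 ± 27.1 bp in control libraries (SD, n = 4 each; log2 -0.26, limma adjusted p = 1.00), and Cldn11, a claudin of myelin, had 708 ± 107 and 817 ± 77.7 bp. All 5 tested endothelial markers were lower (median -0.32, camera adjusted p = 0.191), among them Cldn5, a tight junction gene (-0.52), and Kdr, a growth factor receptor gene (-0.09). Of the developmental transcription factors 6 of 8 were higher (median 0.25, camera adjusted p = 0.294), among them Pax2 (0.30).

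**Figure D1:**
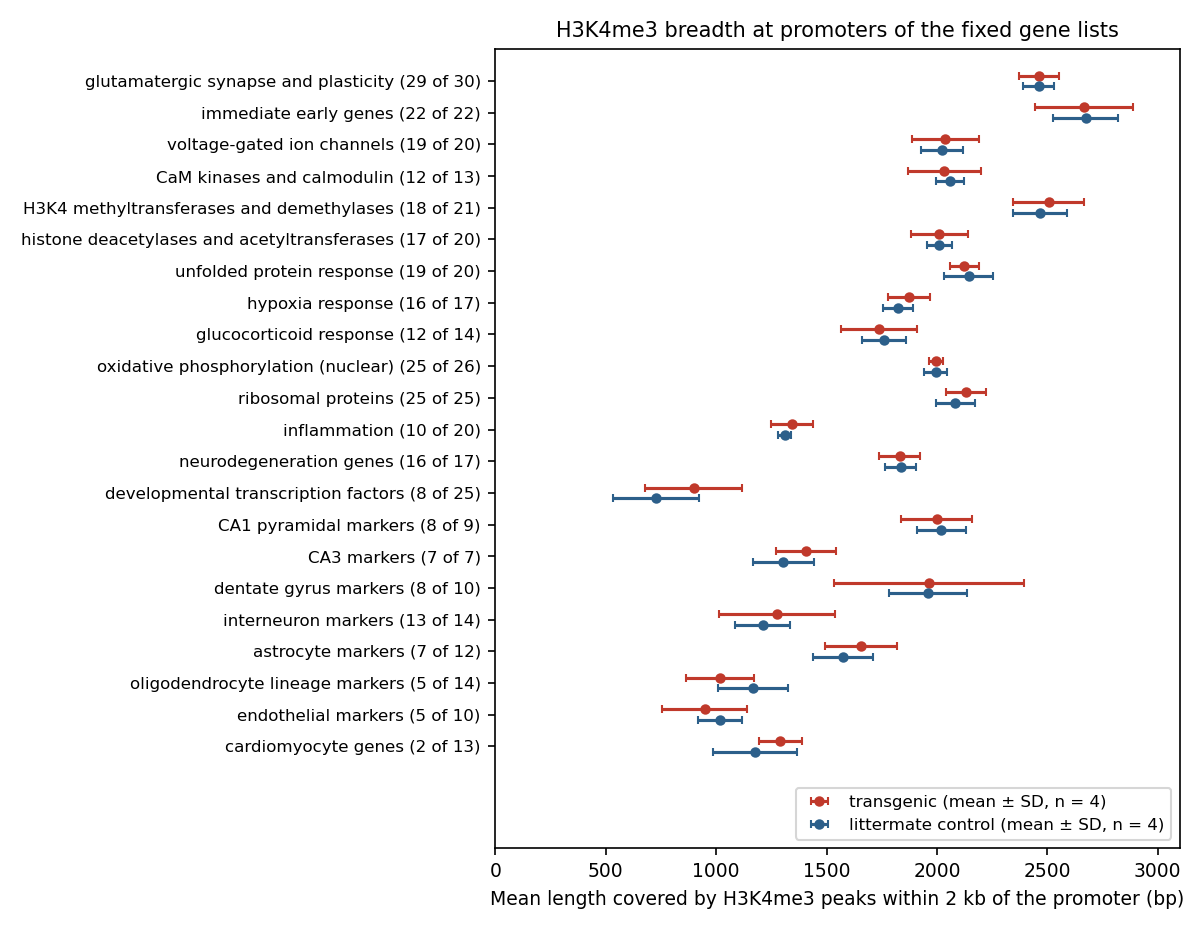
Mean length covered by H3K4me3 peaks within 2 kb of the promoter (bp, horizontal axis) for the tested genes of each fixed list, with points for the group mean over 4 libraries and bars for the SD. Numbers beside each list are genes tested of genes listed, and the bars of both groups overlap in all 22 lists.

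Synaptic promoters had the same mean breadth in both groups, 2461 ± 90.9 bp in transgenic and 2460 ± 72.0 bp in control libraries (SD, n = 4 each), with 9 of 29 tested genes above and 20 below 0 on the centred log2 scale (camera adjusted p = 0.426). The smallest p there belonged to Ntrk2, the BDNF receptor gene (-0.13), and Creb1, a transcription factor gene of memory formation (-0.10). Immediate early genes had 6 above and 16 below 0, with Ier5 at -0.13 and Dusp6, a phosphatase gene, at -0.07. Among ion channel genes 6 were above and 13 below, with the sodium channel gene Scn1a at -0.17 and the potassium channel gene Kcnd2 at 0.08. Of the CaM kinase list 2 were above and 10 below, with Camk1 at 0.13 and Camk2b at -0.24. The deacetylase and acetyltransferase list had 6 above and 11 below, with the acetyltransferase gene Kat2b at 0.14 and the deacetylase gene Hdac2 at -0.12. Among H3K4 enzymes 8 were above and 10 below, with a median of -0.02 while camera gave the list an upward sign (adjusted p = 0.991).

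Stress and metabolic lists likewise did not pass. The unfolded protein response list had 8 members above and 11 below 0, with the chaperone gene Dnajb9 at 0.18 and the transcription factor gene Xbp1 at -0.09. The hypoxia list had 9 above and 7 below, with Car9, a carbonic anhydrase gene, at 1.75 and Adm, which encodes adrenomedullin, at -0.22. Car9 rested on 422 ± 217 bp in transgenic libraries and on a peak of 329 bp in 1 control library. Glucocorticoid-responsive genes had 2 above and 10 below, with Crhr1 at -0.32 and Klf9 at -0.06. Oxidative phosphorylation genes had 9 above and 16 below, with the ATP synthase gene Atp5c1 at -0.16 (limma adjusted p = 0.882) and the succinate dehydrogenase gene Sdha at 0.21. Ribosomal protein genes had 15 above and 10 below, with Rpl5 at -0.25 and Rps3 at 0.21. Inflammatory genes had 6 above and 4 below, with Icam1 at 0.60 and Stat3 at -0.12, and neurodegeneration genes 6 above and 10 below, with Lrrk2 at -0.15.

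Marker genes of cell types did not pass either. CA1 markers had 3 above and 5 below 0, with Neurod6 at -0.07. CA3 markers had 6 above and 1 below, with Cpne4 at 0.35 and Iyd at 0.90, and dentate gyrus markers 1 above and 7 below, with C1ql2 at -0.10 and Calb2 at 0.60. Interneuron markers had 10 above and 3 below, with the GABA-synthesizing enzyme genes Gad1 at 0.21 and Gad2 at -0.27. Astrocyte markers had 4 above and 3 below, with the glutamate transporter gene Slc1a2 at 0.12 and the connexin gene Gja1 at 0.16. The cardiomyocyte genes Tnni3 and Ryr2 stood at 0.89 and 0.04.

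The transgenic lists covered more of the genome outside gene ends. In total they covered 49.4 ± 5.78 Mb against 41.5 ± 2.67 Mb in controls (SD, n = 4 each), a difference of 7.88 Mb in which all 4 transgenic libraries lay above all 4 controls (exact permutation p = 0.0286, the smallest this design allows, adjusted p = 0.171). The difference was 5.09 Mb without transgenic replicate 1 and 3.80 Mb with equal numbers of top-ranked peaks. On the autosomes, examined after the data were seen, peaks away from gene ends covered 20.6 ± 2.79 Mb in transgenic and 15.4 ± 0.985 Mb in control libraries (exact permutation p = 0.0286). Peaks at gene ends covered 24.1 ± 1.37 and 23.1 ± 1.29 Mb (exact permutation p = 0.40). The share of promoters with a peak was 67.6% ± 0.396 and 66.6% ± 0.693 (exact permutation p = 0.0571), a difference that turned to -0.164 percentage points with equal numbers of top-ranked peaks. The number of peaks (73288 ± 19496 and 59728 ± 7576, p = 0.257), their median width (386 ± 25.3 and 376 ± 28.3 bp, p = 0.514), their share at gene ends (29.7% ± 3.88 and 34.2% ± 2.92, p = 0.171) and the number wider than 4 kb (564 ± 145 and 462 ± 110, p = 0.371) did not pass in exact permutation tests. With equal numbers of top-ranked peaks the median width was 512 ± 56.8 and 426 ± 17.8 bp (exact permutation p = 0.0286, adjusted p = 0.0857). That setting kept 51903 peaks per library and so dropped more from the transgenic lists on average. The gap in width may come from this trimming. On the autosomes the share of peaks at gene ends was 33.0% ± 0.18 in transgenic and 37.2% ± 2.01 in control libraries (exact permutation p = 0.0286, adjusted p = 0.0857), a difference of -4.24 percentage points that was -0.965 with equal numbers of top autosomal peaks.

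**Figure D2:**
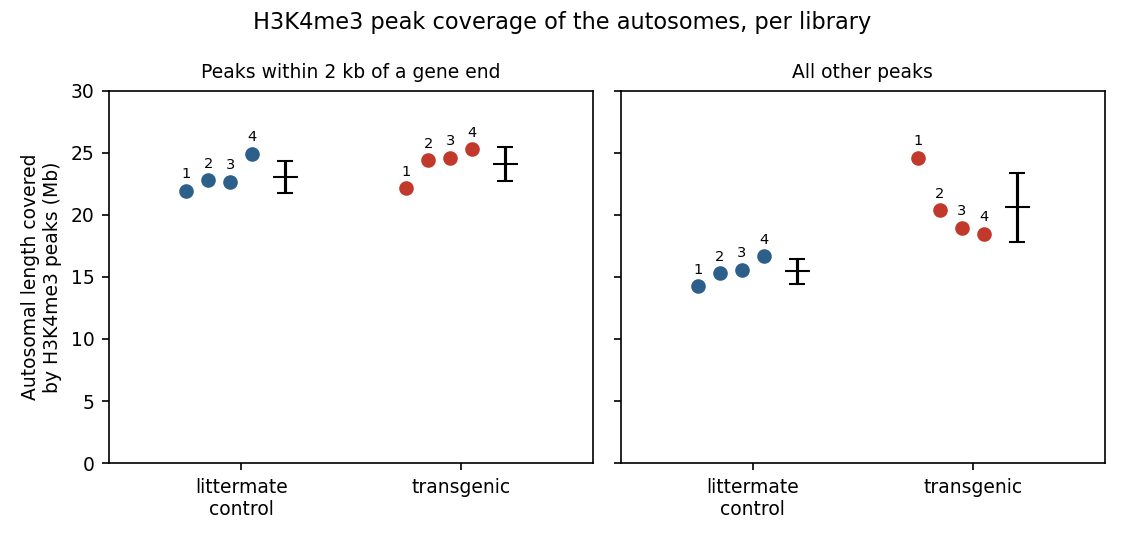
Autosomal length covered by H3K4me3 peaks (Mb, vertical axis) in each library, at gene ends (left) and elsewhere (right), with points numbered by replicate and bars for the mean ± SD of 4 libraries. At gene ends the groups overlap, and elsewhere the 4 transgenic libraries lie above the 4 control libraries.

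Of 72683 regions with a peak in at least 2 libraries, 33 were broader and 2 narrower in the transgenic libraries at an adjusted p of 0.05 in limma. All 35 were autosomal, 28 lay between protein-coding genes and 7 at the ends of such genes. For 15 the nearest protein-coding gene encoded a vomeronasal, olfactory or Mas-related receptor. Some of those between protein-coding genes lay over pseudogenes or in the immunoglobulin heavy chain locus. The regions below were chosen after their values were seen. The smallest p belonged to a region on chromosome 7 (14546151 to 14549843), over the pseudogenes Nlrp5-ps and Obox4-ps3 and 11399 bp from the vomeronasal receptor gene Vmn1r90. It had 2272 ± 502 bp covered in transgenic and 810 ± 160 bp in control libraries (SD, n = 4 each, log2 1.27 ± 0.16, limma adjusted p = 0.00146). A region on chromosome 5 (145907101 to 145909727), 27247 bp from the cytochrome gene Cyp3a11, had 1583 ± 400 and 377 ± 96.2 bp (limma adjusted p = 0.00425). A region on chromosome 17 (37884669 to 37886691), 16857 bp from the olfactory receptor gene Olfr127, had 1298 ± 154 and 244 ± 52.5 bp (log2 1.92), and a region in the immunoglobulin heavy chain locus on chromosome 12 (115658022 to 115660580) had 2306 ± 123 and 1162 ± 321 bp (log2 0.86).

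Regions at gene ends that passed included Mrgpra1, an itch receptor gene (chromosome 7, 47334104 to 47336712, log2 1.14), Psg18, a pregnancy-specific glycoprotein gene (chromosome 7, 18354283 to 18356626, log2 1.23), and Cyp2b19 (log2 0.90). The 2 narrower regions lay at gene ends, over Slc5a3, an inositol transporter gene, with Mrps6 (chromosome 16, 92057279 to 92061355, log2 -0.41 ± 0.08, limma adjusted p = 0.0385), and over Pde4a, a cAMP phosphodiesterase gene (chromosome 9, 21163849 to 21168874, log2 -0.30 ± 0.06, limma adjusted p = 0.0386). At both the groups overlapped, unlike at the 33 broader regions. At Slc5a3 control replicate 3 had 2715 and transgenic replicate 4 had 2819 bp. At Pde4a control replicate 1 had 4012 and transgenic replicate 4 had 4314 bp. Without centring, with either other pseudocount, on autosomes or without any single transgenic library, 0 regions were called narrower. Array weights gave 8 and leaving out control replicate 4 gave 3. The count of 35 fell to 0 with equal numbers of top-ranked peaks, to 0 with a replicate block, to 0 for regions with peaks in at least 4 libraries, to 10 on autosomes alone and to 15 without transgenic replicate 1, and rose to 118 without centring and to 54 without control replicate 3. Of the 35, 34 had a peak in all 8 libraries and the other in 7. The limits to autosomes and to at least 4 libraries thus removed none of them, and those lower counts came from refitting the regions kept. Many of these genes belong to families of similar copies, where 50-bp reads are placed with less certainty. There was 1 background sample per genotype, and which of them served which list is not given.

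By presence alone, 288 regions had a peak in all 4 transgenic and in no control library, and 13 the reverse, of which 0 passed in the limma fit above. Of the 288, 215 lay between protein-coding genes, 42 inside them and 31 at their ends. Some of the 215 lay over pseudogenes, noncoding RNA genes or the immunoglobulin heavy chain locus. The median covered length of the 288 was 328 bp, against 304 bp for the 13. The widest found in transgenic libraries alone lay inside Olfm1, a neuronal olfactomedin gene (chromosome 2, 28198709 to 28200229, 847 ± 346 bp; SD, n = 4), beside Aadacl4fm3, an arylacetamide deacetylase-like gene (chromosome 4, 144698754 to 144700013, 762 ± 302 bp), and beside Serpinb9g, a protease inhibitor gene (chromosome 13, 33498159 to 33499300, 672 ± 348 bp). The widest found in control libraries alone lay over the long noncoding RNA gene Gm35125 (chromosome 17, 83873597 to 83874288, 354 ± 227 bp), near the start of chromosome 9 (3002822 to 3003168, 344 ± 2.0 bp) and inside Tcf4, a transcription factor gene (chromosome 18, 69601034 to 69601717, 336 ± 50.2 bp). With equal numbers of top-ranked peaks the counts were 103 and 26. With any library left out they were between 449 and 803 and between 26 and 67. Leaving out a library loosens the rule, so these counts could not fall and say nothing on stability.

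The sex chromosomes divided the libraries in a way the labels do not give, since all 8 are labelled male. Xist, the RNA gene that silences an X chromosome, had a promoter peak in control replicates 2 and 3 (2664 and 2370 bp) and in transgenic replicates 1 and 4 (2685 and 2632 bp), and in no other library. These libraries had 13559, 13023, 31362 and 13552 peaks on the X chromosome, the others between 1145 and 1293. The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y had promoter peaks in control replicates 1 and 4 and in transgenic replicate 3, which had 1024, 1072 and 1220 peaks on the Y chromosome. Transgenic replicate 2 had neither an Xist peak nor a peak at these Y-linked promoters, with 1280 X and 6 Y peaks. Each group held 2 libraries with the Xist peak. In a fit of the autosomes alone 10 regions passed, although all 35 called above were autosomal, and 286 and 13 autosomal regions occurred in 1 group alone.

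**Figure D3:**
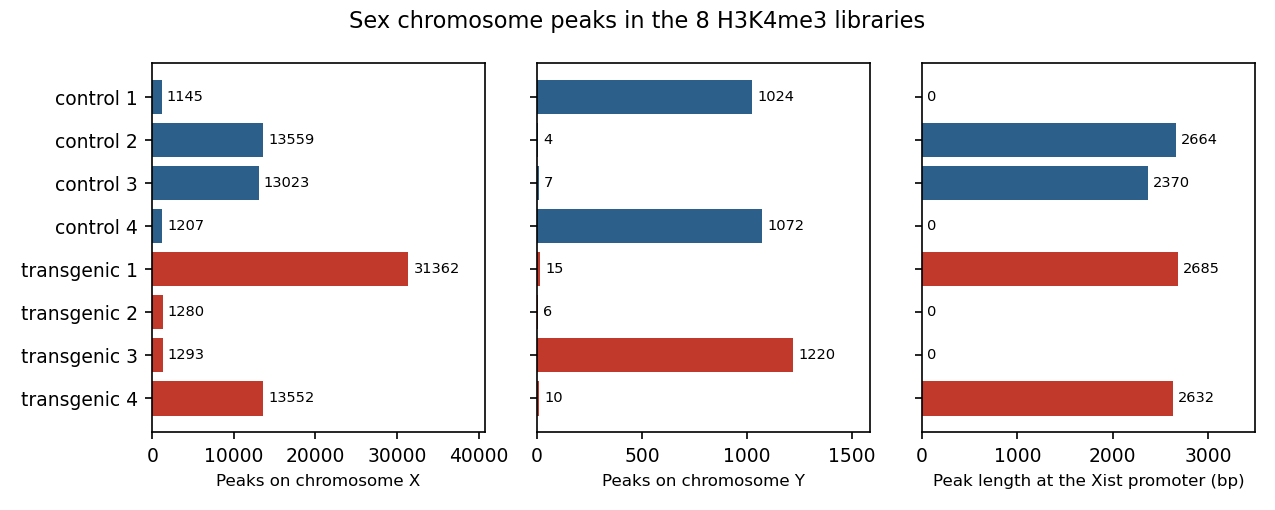
Peaks on the X and Y chromosomes and peak length at the Xist promoter (bp), as bars for each of the 8 libraries. The 4 libraries with an Xist peak have 13023 to 31362 X peaks and at most 15 Y peaks.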

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

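The tests on the X chromosome and on the peak number of transgenic replicate 1 were chosen after the results were seen. A sample was looked at again where its distance to the nearest of its group exceeded the 95% critical share of the group's whole range in Dixon's test. Of 140 groups of values 9 met this, where chance gives about 7, and 5 of the 9 were transgenic replicate 1.

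Transgenic replicate 1 had 102285 peaks, the other transgenic libraries between 60388 and 66560. Its promoters were narrower than those of its group at Ier5 (1640 bp, others 2021 to 2039), C1ql2 (1406 bp, others 2281 to 2345), Gad2 (475 bp, others 1068 to 1177) and Camk2d (1142 bp, others 1538 to 1590). On the autosomes alone its distance in peak number was 0.462 of the range (70908 peaks, others 52998 to 62635), so its X chromosome peaks may account for its standing apart in the total, while its autosomal number was still the highest. No biological explanation was tested for this library.

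Control replicate 1 covered 37.5 Mb, the other controls between 42.7 and 43.1 Mb. Control replicate 2 had 2157 bp at Ier5, the other controls 2048 to 2064. Control replicate 4 alone among controls had a peak at Car9 (329 bp) and Tnni3 (310 bp).

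In 4 libraries, 2 of each group, over 10000 peaks lay on the X chromosome. In 8 of 8 libraries a peak at the Xist promoter was present exactly where X peaks exceeded this number, and never together with a peak at the promoters of Kdm5d, Eif2s3y, Uty or Ddx3y, which is consistent with nuclei holding an inactive X in the 4 libraries, against the male label. The X peaks of these 4 libraries had median widths of 250 to 273 bp, against 471 to 525 bp in the others. Why they were so many was not tested. A mixture of nuclei of both sexes within a library is argued against, since 0 libraries had both the Xist peak and a Y promoter peak. Lists called less strictly on every chromosome are argued against too, since the mean number of autosomal peaks was only 1.03 times that of the other 4. Transgenic replicate 2, with neither Xist nor Y promoter peaks, stays unplaced, and whether labels or samples were exchanged stays open.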

How the results depend on the processing

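Array weights, the whole gene as window, autosomes alone, equal numbers of top autosomal peaks and the X covariate were added after seeing the data, and the cause of a change was not tested. The limits to autosomes and to at least 4 libraries took none of the 35 called regions out of the fit. The planned promoter at the gene's first annotated start site was not run, since no strand was used here, and the number of peaks has no value where equal numbers are kept. The count of 0 promoters held in all settings except limma with ordinary variances (5). The count of 0 lists became 1 without centring. Against 35 regions, limma called 118 without centring, 15 with a pseudocount of 10 bp, 12 with peaks within 500 bp merged, 57 with array weights, 10 on autosomes, 2 with equal top autosomal peaks, 21 with the X covariate, and 0 with equal top peaks and for at least 4 libraries. Leaving out a library gave 15 (without transgenic replicate 1) to 54 (without control replicate 3). Of the 35, 33 were shared with no centring, 33 with array weights, 17 with the X covariate, 15 with a pseudocount of 10 bp and 12 without transgenic replicate 1. With peaks within 500 bp merged 1 was shared, and with equal top autosomal peaks 1. In those settings regions were formed anew and counted as shared only with identical start and end. Both counts may therefore be too low and do not show that other places were called. Same-numbered libraries did not deviate together (correlations -0.0632, -0.129, -0.162 and 0.166), so the numbers do not pair the samples, and the fit with a replicate block called 0 regions and 0 promoters. Regions in transgenic libraries alone numbered 466 with at least 50% of the region covered, 103 with equal top peaks, 161 with peaks within 500 bp merged, 109 with equal top autosomal peaks, and 449 to 803 with a library left out. Regions in controls alone numbered 26 with equal top peaks, 27 with equal top autosomal peaks, and 26 to 67 with a library left out. For both groups, leaving out a library loosens the rule, so the counts could not fall. The difference in promoters with a peak turned to -0.164 percentage points with equal top peaks and -0.1996 with equal top autosomal peaks. The other summaries kept their direction, but the difference in covered length, 7.88 Mb, was 5.09 without transgenic replicate 1, 3.80 with equal top peaks and 3.6 with equal top autosomal peaks, and that in peak number, 13561, was 3895 without transgenic replicate 1 and 7442 with peaks within 500 bp merged. The difference in median width, 9.5 bp, was 85.2 with equal top peaks, 84.5 with equal top autosomal peaks, 33.6 with merging and 1.33 to 19.5 with a library left out. The difference in peaks wider than 4 kb, 102, was 424 with merging and 43.5 to 162 with a library left out, and that in the share at gene ends, -4.50 percentage points, was -0.884 with equal top peaks, -0.965 with equal top autosomal peaks, -2.84 with merging and -2.96 without transgenic replicate 1. Of 933 log2 differences of named promoters under other settings, 913 kept their sign and 0 passed (smallest adjusted p 0.0568). Signs turned with the whole gene as window for Ntrk2 (0.055), Ier5 (0.0105), Dusp6 (0.0224), Gad2 (0.00767), Camk2d (0.10), Camk2a (0.16), Kmt2a (0.0351), Kmt2d (0.0236), Bdnf (-0.0215) and Fos (0.00664), with 5 kb for Ier5 (0.00694), Dusp6 (0.0214), Bdnf (-0.0129) and Fos (0.00409), with 1 kb for Adm (0.33), Camk2d (0.28) and Camk2a (0.0303), with equal top peaks for Gad1 (-0.11), and for Camk2d with array weights (0.0395) and without centring (0.0068). With a library left out the values ran from -0.16 to 0.036 for C1ql2, -0.00231 to 0.0775 for Ryr2, -0.0502 to 0.0532 for Camk2d, -0.0826 to 0.0306 for Camk2a, -0.0189 to 0.0911 for Kmt2b and -0.12 to 0.0304 for Arc. Depth is unknown, so whether a region without a peak lacks the mark or reads cannot be judged.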

Other observations

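The gene families below, the counts of splits for autosomes and for olfactory receptors, and the tests that left out transgenic replicate 1 or bear on the control libraries were chosen after the results were seen.

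Families of sensory receptor genes, which CA1 neurons are not known to use, had more promoter length covered by H3K4me3 peaks in the transgenic lists. Of 1110 olfactory receptor genes 238 could be tested, and 211 of them lay above 0, with a median log2 difference of 0.84 (camera adjusted p = 1.82e-34 over 5 families, 0.0284 with an estimated correlation). A gene could pass the limit of 4 libraries through the transgenic lists alone. The median was 0.62 over the 75 genes with a peak in all 8 libraries and 0.53 over the 448 with a peak in at least 1. It was 0.46 with a pseudocount of 500 bp and 1.32 with 10 bp. With that correlation the family no longer passed 0.05 with a replicate block (0.0808) or without control replicate 1 (0.0586), 3 (0.0506) or 4 (0.0586), and in these fits neither did the families named next. The median promoter of the family had 596 ± 184 bp covered in transgenic and 265 ± 49.6 bp in control libraries (SD of the library medians, n = 4 each). Vomeronasal receptors of type 1 (median 0.68, 65 of 69 above 0) and type 2 (0.85, 57 of 61) and pregnancy-specific glycoproteins (0.50, 13 of 13; 0.27 without transgenic replicate 1) also lay above 0, while 367 zinc finger genes named Zfp had a median of 0.01. Both vomeronasal families (adjusted p = 0.0284 each at that correlation) also failed with quantile normalization (0.057 each) and without control replicate 2 (0.0628 each), and type 2 without transgenic replicate 2 (0.0651). Regions present in transgenic libraries alone lay on chromosome 7 in 31.1% of 286 autosomal cases, against 22.8% of other autosomal regions with a peak in 4 libraries (Fisher's exact test, adjusted p = 0.036 over chromosomes). That test counts regions as independent, but many of those on chromosome 7 lay in the same gene clusters, so its p may be too small. A region near the start of chromosome 17 (3005822 to 3023923), picked for its size, had 14268 ± 1775 bp in transgenic and 8689 ± 830 bp in control libraries (SD, n = 4 each).

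A hypothesis is that chromatin of silent receptor clusters may carry more H3K4me3 in the transgenic samples. With equal numbers of top autosomal peaks the olfactory median was 0.57 and all 4 transgenic library medians lay above all controls, which argues against the number of peaks alone as the whole source. The peaks kept were wider in transgenic than in control libraries (medians of 510.5 ± 52.7 and 426 ± 14.7 bp, SD). In the full autosomal lists the medians were 419 ± 13.9 and 405.5 ± 3.70 bp (exact permutation p = 0.171). Keeping equal numbers dropped more peaks from the transgenic lists on average, so the wider gap may come from the trimming itself. A difference in depth or precipitation, which changes widths too, stays open. Of 1000 random gene sets matched on covered length 0.0% had a median as large (median of the sets 0.04), which argues against weak marking of any gene as the whole source. These sets drew scattered genes independently, whereas the genes of the family moved together (estimated correlation 0.14). The family was also picked for its values, so this share does not measure chance. Without transgenic replicate 1 the median was 0.63 over 204 genes. The criterion, all 3 other transgenic library medians above all controls, was read over the 238 genes tested with all 8 libraries. It was missed by transgenic replicate 4 beside control replicate 1 (8.80 and 8.81 on the centred log2 scale). In tests added after that miss, olfactory receptors met the same criterion with equal numbers of top autosomal peaks. Their median was 0.56 without replicate 1, with 9.17 in transgenic replicate 4 and 9.03 in control replicate 1. On all peaks vomeronasal receptors of type 1 (0.37) and type 2 (0.46) met it. The library medians were already known when these tests were added, so their outcome could be foreseen. They show only that, in these families and settings, replicate 1 was not the only transgenic library above all controls. Each genotype had 1 background library. If it served the lists of its own genotype, its effect on the peaks cannot be told apart from genotype. Reads shared between similar gene copies stay open, untested. Of the 35 splits of the 8 libraries 2 gave an olfactory median as large (0.84, highest other 0.91 for transgenic replicates 1, 2 and 3 with control replicate 1), so chance was not excluded.

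Other splits of the 8 libraries bear on the counts. For the 0 promoters past the threshold (35 of 35 splits, highest other 30) and the 0 gene lists (35 of 35, highest other 3) the count of splits says nothing on chance, since no split can give fewer than 0. Chance was not excluded for the 608 promoters with an unadjusted p under 0.05 (17 of 35, highest other 1861, transgenic replicate 1 with control replicates 1, 2 and 3), the 35 regions (2 of 35, highest other 118) or the 301 regions present in 1 group alone (2 of 35, highest other 1276). The highest other values of 30, 118 and 1276 came from the split that follows the X chromosome peaks, which points to a structure of the samples. On autosomes, chosen after these counts, the real split alone (1 of 35, the lowest share possible) gave as many as 10 regions (highest other 3) and 299 regions in 1 group alone (highest other 208). This share is under 0.05, but the test followed the misses on all chromosomes and only 2 regions passed with equal numbers of top autosomal peaks, where other splits were not counted, so chance is not firmly excluded.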
